A study of Rattus norvegicus with 12 samples.

How the data were processed

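Gene counts were analysed for 12 RNA-seq libraries of primary rat pulmonary artery smooth muscle and endothelial cells, with 3 libraries in each of 4 groups (cell type by siRNA). Groups and replicate numbers were taken from the sample titles, since the cell type label reads PASMC for all samples. The columns of the count table carry abbreviated names, not the titles. They were matched to the titles by reading their letters as E for endothelial and S for smooth muscle cells, then C for the control siRNA and S for the NRF2 siRNA, with the replicate number. This reading is an inference that no label states, the direction of every comparison rests on it, and the level of the siRNA target could not be used to check it. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a directional (strand-keeping) kit. The deposited table holds whole-number counts per gene that are not normalized, with exon coordinates and a length for each gene. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 2.0.3 and DESeq2 1.32.0 were used. The notes give no roles or settings. The genome build and whether counting used strand are not given in the sources used here, so counts of overlapping genes, on the same or opposite strands, may share reads. Counts of near-identical gene copies may likewise be split or lost, depending on how reads with several matches were treated.

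The table lists 32883 genes by Ensembl ID. None of these IDs (0 of 32883) could be matched to a symbol with the gene table used here (assembly GRCr8), which holds no Ensembl IDs for this organism. The rule set for named genes before the data were examined, which took the largest changes among genes with a symbol, named none. The 31 gene lists fixed by symbol and the check of the siRNA target's own transcript were not run. After the table was seen to hold no symbols, and before any test, a second rule was set. It prints the 2 genes with the largest rise and the 2 with the largest fall in both cell types, by the smaller of the changes, among genes called in both, with a mean of at least 2 CPM in each cell type and no overlap between siControl and siNRF2 values in either. Of the genes eligible, 434 rose and 406 fell. Gene groups that need no symbol were set at the same time, as chromosomes, mitochondrial genes of at least 200 bases, single-exon genes, cell-type-enriched genes (at least 8-fold higher among siControl libraries) and regions of 3 or more consecutive tested genes that are all called in the same direction and changed by at least 2-fold. After the first results were seen, the cell-type-enriched genes were set anew as those at least 8-fold higher under both siRNAs. Positions are given as in the count table, counted from 1, with a gene running from the start of its first exon to the end of its last. Single regions, mitochondrial genes and libraries described in the text were chosen after their values were seen.

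Genes were kept by edgeR's filterByExpr on the 4 groups, which left 14584. Libraries were scaled by TMM. A model with 1 coefficient per group over all 12 libraries (8 residual degrees of freedom) was fitted with edgeR 4.0.16 (estimateDisp, glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The 4 contrasts were siNRF2 against siControl in PASMC and in PAEC, the difference between these effects (the interaction), and PAEC against PASMC in siControl. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the F statistics. Values in CPM used TMM library sizes, and log2 CPM a prior count of 2. Gene groups were tested on voom values with camera (preset correlation 0.01, and with an estimated correlation) and fry in limma 3.58.1. The number of regions was compared with 1000 shuffles of the calls over the tested genes. Local gene density was the number of genes in the table with their midpoint within 500 kb on either side of a gene's midpoint. As a setting added after seeing the data, the lowess trend of each library with this density, relative to the mean of the cell type, was entered as an offset in the edgeR fit. Mitochondrial genes have no such density, so that offset leaves them as they were.

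The depth was 27008812 to 34317763 counts per library. Replicates of a group differed by more than sampling noise (chi-square per gene from 9.11 to 42.4), so none were counted as duplicates. Log2 CPM of replicates correlated at 0.976 to 0.984, those of different siRNAs in a cell type at 0.966 to 0.974, and those of different cell types at 0.880 to 0.897.

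The steps were tested on simulated data, drawn for the 14584 genes from the observed means, dispersions and library sizes with 200 genes changed. For the PASMC comparison, edgeR recovered 47.8% of genes changed by 1.5-fold, 52.2% of those changed by 2-fold and 83.3% of those changed by 4-fold, and 4.69% of its calls were false. For the PAEC comparison it recovered 46.3%, 67.2% and 81.8%, and 6.48% of its calls were false. With a gene density slope of 0.15 simulated in PASMC siNRF2 libraries, the fit without the offset made 294 false calls and the fit with it 9. Planted sets and runs of genes were recovered. Far more genes were called in the data than were changed here, so these shares of recovered and false calls need not hold there.

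Alternatives fixed at the same stage as the first rule were DESeq2 size factors (DESeq2 1.42.0), library totals without TMM, the DESeq2 Wald test, limma voom, no filter on low counts (20254 genes), at least 10 counts in every library of a group (13939 genes), the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a change of at least 2-fold, and only the 6 libraries compared. Other assignments of the siRNA and cell type labels were refitted, with 10 splits for each comparison of 3 against 3 and 100 for the interaction.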

Results

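RNA was sequenced from primary rat pulmonary artery smooth muscle cells (PASMC) and pulmonary artery endothelial cells (PAEC), the contractile cells of the vessel wall and the cells that line it. Each cell type had received either a control siRNA (siControl) or an siRNA against NRF2 (siNRF2), a transcription factor that drives genes of the oxidative stress response. An siRNA is a short double-stranded RNA that lowers the mRNA it matches. Each of the 4 groups held 3 libraries, which the design text calls biological replicates. The sources used here do not say whether they were separate animals or cultures, so p-values of group comparisons measure the spread between these libraries. Gene counts summed to 30381300 ± 3657320 per library in PASMC siControl, 31424434 ± 991637 in PASMC siNRF2, 31657500 ± 1205440 in PAEC siControl and 32511800 ± 1566810 in PAEC siNRF2 (mean ± SD, n = 3 each). Individual libraries ranged from 27008812 to 34317763 counts. On principal component analysis of log2 CPM (counts scaled to a common library size), the first component held 67.0% of the variance and separated the cell types. The second, with 6.72%, separated the siRNAs in PAEC, and the third, with 5.77%, separated them in PASMC. The third also spread the libraries of PAEC siControl, from -16.25 for replicate 1 to 17.08 for replicate 3. The abbreviated column names of the count table were matched to the groups by their letters, a reading that no label states and on which every direction given here rests. The count table names genes by Ensembl ID and does not pair them with symbols. The level of the siRNA target and the 31 gene lists planned by symbol are therefore not analysed here, and genes are described by ID, chromosome or position.

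The first comparison asked which genes changed in smooth muscle cells given the NRF2 siRNA. In PASMC, 2350 of 14584 genes tested rose and 2129 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). With library totals in place of TMM factors, 1979 rose and 2483 fell, so the balance of rises and falls depended on the scaling. The median absolute log2 fold change of the called genes was 0.49, and 150 rose and 187 fell by at least 2-fold. Among changes of at least 4-fold, 43 genes rose and 38 fell. The 15 mitochondrial genes of at least 200 bases fell from 2.98 ± 0.329% of all counts in siControl to 1.60 ± 0.142% in siNRF2 (mean ± SD, n = 3).

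The same comparison in endothelial cells called 1678 genes that rose and 1929 that fell, or 1351 and 2228 with library totals. Decreases outnumbered increases among the larger changes, with 418 genes falling and 168 rising by at least 2-fold, and 109 falling and 44 rising by at least 4-fold. The median absolute log2 fold change of called genes was 0.51. The 15 longer mitochondrial genes took 3.83 ± 0.652% of counts in siControl and 4.61 ± 0.203% in siNRF2. The 10 most abundant genes of each library took 11.4 ± 0.197% of counts in PAEC siControl and 13.1 ± 0.284% in PAEC siNRF2, against 5.50 ± 0.236% and 5.28 ± 0.0580% in PASMC.

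The genes that changed in both cell types were then compared. The comparisons share no library. In both cell types 459 genes rose, where independent lists of these sizes would share 270.4, and 452 fell, where 281.6 would be shared (Fisher's exact test over genes, two-sided, odds ratio 2.19, p = 1.04e-35 for rises and odds ratio 2.0, p = 7.64e-29 for falls). Genes are not independent replicates. With library totals in place of TMM factors, a setting added to this comparison after the data were seen, 341 genes rose and 573 fell in both. By at least 2-fold, 13 genes rose in both and 38 fell in both. A further 619 genes moved in opposite directions, with 374 higher in PASMC and lower in PAEC and 245 the other way, where independent lists would give 555.8. Without PAEC siControl replicate 2, the number with opposite directions was 407. Over all tested genes the log2 fold changes of the cell types had a Pearson correlation of 0.026 and a Spearman correlation of 0.00089, across genes.

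**Figure D1:**
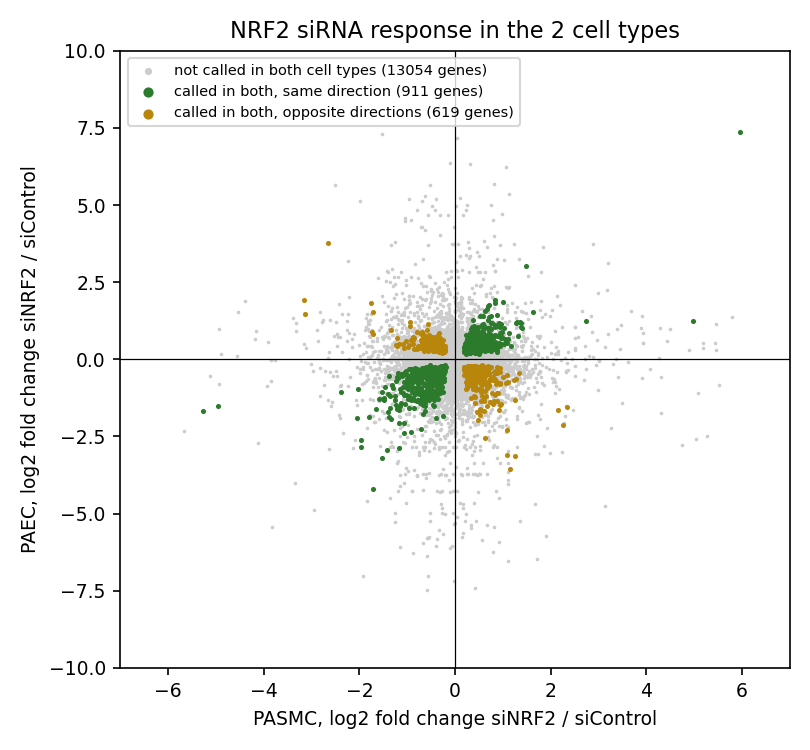
Each point is 1 of 14584 genes, with the log2 fold change of siNRF2 over siControl in PASMC on the x axis and in PAEC on the y axis. Green points mark the 911 genes called in the same direction in both cell types and yellow points the 619 called in opposite directions. Fold changes of genes with few counts depend on the prior count of the fit.

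Of the genes that rose in both cell types, ENSRNOG00000007089 (chromosome 6, 126282233 to 126320726, minus strand, 14 merged exons) went from 103 ± 9.29 to 289 ± 8.72 CPM in PASMC and from 93.3 ± 7.46 to 761 ± 40.8 CPM in PAEC (mean ± SD, n = 3). The log2 fold change was 1.49 (SE 0.080, adjusted p = 1.8e-09, edgeR) in PASMC and 3.03 (SE 0.085, adjusted p = 3.1e-14) in PAEC. The rise was larger in PAEC, by 1.54 on the log2 scale (adjusted p = 4.5e-08). ENSRNOG00000047046 (chromosome 9, 10963723 to 10971277, plus strand) rose by similar amounts, 1.64 (SE 0.20, adjusted p = 1.5e-05) in PASMC and 1.54 (SE 0.20, adjusted p = 1.3e-05) in PAEC, from 2.89 ± 0.667 and 7.94 ± 1.71 CPM in siControl. The interaction gave an adjusted p of 0.84 for this gene.

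Of the genes that fell in both, ENSRNOG00000026607 (chromosome 13, 79378733 to 79388498, plus strand) went from 9.12 ± 2.43 to 2.31 ± 0.653 CPM in PASMC and from 15.3 ± 2.09 to 2.13 ± 0.715 CPM in PAEC. Its log2 fold changes were -1.98 (SE 0.27, adjusted p = 3.6e-05, edgeR) and -2.85 (SE 0.28, adjusted p = 5.9e-07). The difference between them did not pass the threshold (adjusted p = 0.092). ENSRNOG00000029668 (chromosome 10, 71047310 to 71053191, plus strand) had log2 fold changes of -1.72 (SE 0.34, adjusted p = 0.00079) in PASMC and -4.21 (SE 0.41, adjusted p = 5.4e-07) in PAEC, where it went from 5.24 ± 1.83 to 0.279 ± 0.167 CPM. The fall was larger in PAEC (interaction log2 fold change -2.49, SE 0.52, adjusted p = 0.0018).

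The difference between the cell types in their response to the siRNA was tested directly as an interaction. The effect differed for 4239 genes, with the PAEC effect above the PASMC effect for 1989 and below it for 2250. Among differences of at least 2-fold, 333 were above and 573 below. All 619 genes called in opposite directions were among the 4239 (edgeR, adjusted p under 0.05). This follows almost by construction, since called effects of opposite sign differ by more than either effect. Of the 911 genes called in the same direction, 182 differed in the size of the effect.

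The 15 longer mitochondrial genes were then compared between the cell types. In PASMC 14 fell and 0 rose over all genes tested, and 15 fell when adjusted over the list alone, with a median log2 fold change of -1.26. In PAEC 5 rose and 0 fell over all genes tested, and 9 rose when adjusted over the list alone, with a median of 0.43. The count in PAEC depended on single libraries, at 9 without siControl replicate 3, 3 without siNRF2 replicate 2 and 2 without any 1 of the other 4 libraries, and on the setting, at 8 with the DESeq2 Wald test, 9 with limma voom and 3 with no filter on low counts. The interaction was called for 14 of the 15 genes, with a median of 1.81. The set test (camera, preset correlation 0.01, adjusted over all groups tested) gave an adjusted p of 1.3e-12 in PASMC, 0.00022 in PAEC and 9.4e-15 for the interaction. With an estimated correlation the adjusted p was 0.21, 0.57 and 0.14, respectively. The directional test of the set alone (fry) gave adjusted p values of 0.00056, 0.055 and 0.00043. The genes at positions 68 to 1025 and 1094 to 2664 moved least in PASMC, with log2 fold changes of -0.31 (SE 0.12, adjusted p = 0.067, edgeR) and -0.51 (SE 0.095, adjusted p = 0.00056). The largest fall in PASMC was -2.46 (SE 0.43), at positions 7758 to 7961, whose span overlaps the next gene. This gene had the lowest level of the 15 in PASMC, at 2.20 ± 1.06 CPM in siControl and 0.397 ± 0.00267 in siNRF2. The next largest fall was -1.75 (SE 0.21) at positions 7006 to 7689, from 1850 ± 439 to 551 ± 63.5 CPM.

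**Figure D2:**
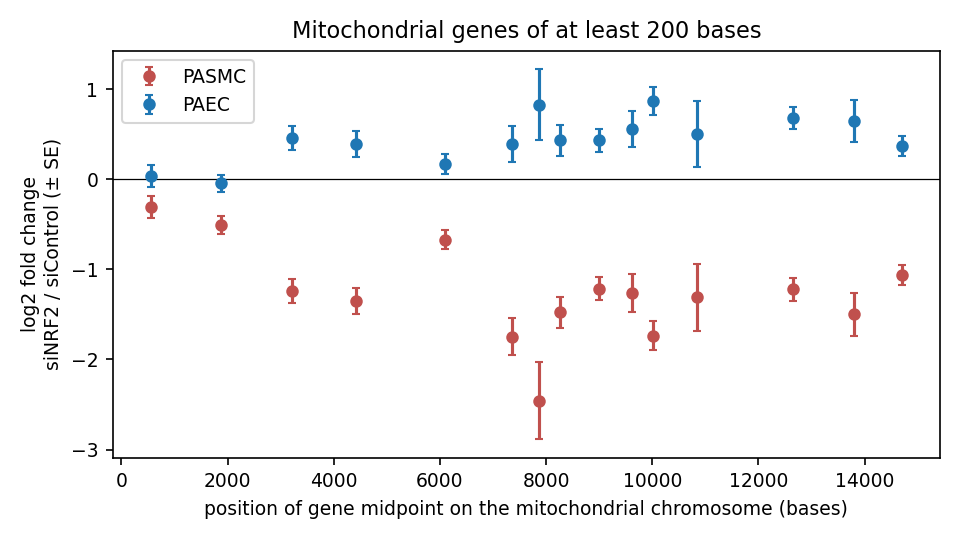
Log2 fold change of siNRF2 over siControl (y axis, ± SE from the edgeR fit) for the 15 mitochondrial genes of at least 200 bases, by the position of their midpoint in bases (x axis), in PASMC (red) and PAEC (blue). All 15 values lie below 0 in PASMC, and 14 of 15 lie above 0 in PAEC.

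Genes that changed by at least 2-fold were also neighbours on the chromosomes more often than chance would give. In PAEC 7 regions of 3 or more consecutive tested genes fell together and 0 rose, where shuffled calls gave a mean of 0.351 regions (permutation p = 0.0010, the smallest that 1000 shuffles can give). In PASMC 2 regions fell together, where shuffled calls gave 0.049 (permutation p = 0.0030). Both PASMC regions hold a pair of overlapping genes on the same strand, which the shuffles treat as independent, so this excess rests on regions whose counts are not shown to be separate. The number in PAEC was 3 with no filter on low counts, 4 with only the 6 PAEC libraries in the fit and 4 without siControl replicate 2. In PASMC it was 1 with no filter. Coordinates are those of the count table, whose genome build is not given in the sources used here.

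The region on chromosome 10 from 70964396 to 71053191 held 3 genes, including ENSRNOG00000029668, that fell in both cell types, with a median log2 fold change of -1.42 in PASMC and -2.94 in PAEC. The first gene spans the second on the same strand, and whether their counts share reads is not given in the sources used here. On chromosome 20, 4 genes between 3176107 and 3249189 moved in opposite directions. They fell in PAEC by a median log2 fold change of -2.39 (range -3.14 to -1.47, adjusted p at most 5.9e-06, edgeR) and rose in PASMC by a median of 1.01 (range 0.61 to 1.25, adjusted p at most 0.015). All 4 also passed the interaction test, as called effects of opposite sign nearly always do. With single PASMC libraries left out, 3 or 4 of them were called in PASMC, 3 of them without siControl replicate 1. The most abundant of them, at 3176107 to 3179818, went from 275 ± 25.2 to 99.5 ± 8.63 CPM in PAEC and from 207 ± 26.3 to 399 ± 13.7 CPM in PASMC. With each library's trend with local gene density removed, a setting chosen after the data were seen, the PASMC median was 0.73 (median SE 0.12) and 2 of the 4 genes were called there, while the 4 were called in PAEC with a median of -2.28.

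**Figure D3:**
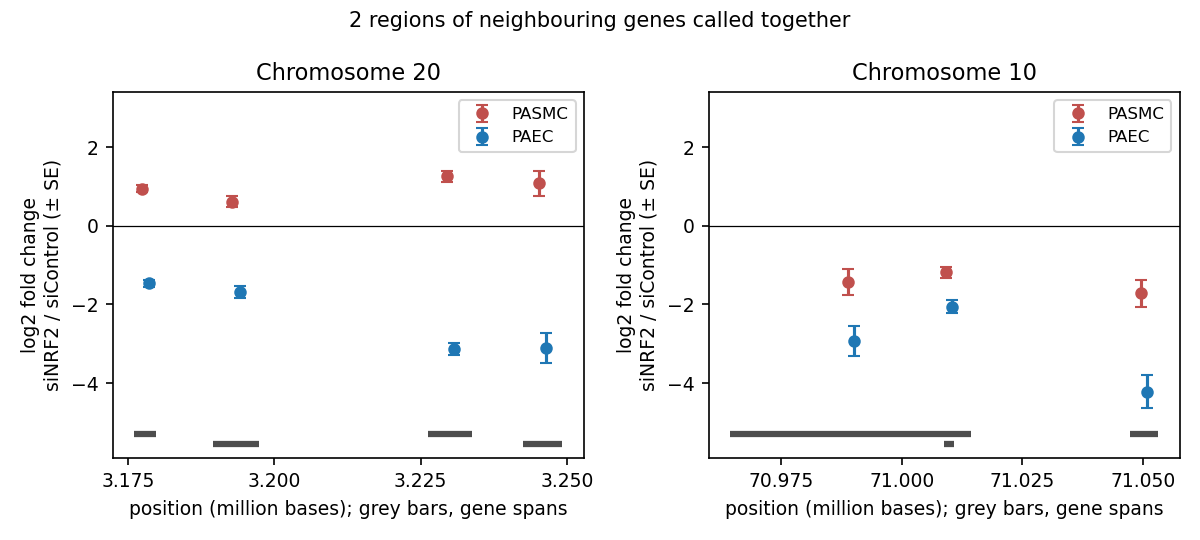
Log2 fold change of siNRF2 over siControl (y axis, ± SE from the edgeR fit) by position in Mb (x axis) for the 4 genes of the chromosome 20 region and the 3 of the chromosome 10 region, in PASMC (red) and PAEC (blue), with gene spans as grey bars. The chromosome 20 genes lie above 0 in PASMC and below 0 in PAEC, and the chromosome 10 genes lie below 0 in both.

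On chromosome 11, between 37798370 and 38059950, 3 genes fell in PAEC by a median of -1.75, and 2 of them rose in PASMC. On chromosome 14, 3 genes between 17195014 and 17234712 fell in PAEC by a median of -2.20. The middle gene of these, at 17210733 to 17212930, went from 77.6 ± 11.6 to 21.6 ± 0.891 CPM in PAEC, with a log2 fold change of -1.84 (SE 0.097, adjusted p = 3.7e-10, edgeR). In PASMC it was at 1307 ± 36.5 CPM in siControl and its log2 fold change was -0.26 (SE 0.089, adjusted p = 0.035). The second region that fell in PASMC, on chromosome 19 from 15033108 to 15366079, held 3 genes with a median of -2.04, of which 2 also fell in PAEC. The first and second of these genes overlap on the same strand. The second had few counts in PASMC, at 0.364 ± 0.169 CPM in siControl and 0.0366 ± 0.0317 in siNRF2. The region rests on this gene to reach 3.

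On some chromosomes rises and falls were uneven in PASMC, though most of the genes tested there were not called. On chromosome 12, 123 genes rose and 29 fell, and on chromosome 20, 115 rose and 33 fell. On chromosome 2, 75 rose and 225 fell, and on the X chromosome, 37 rose and 114 fell. The median log2 fold changes of these chromosomes were 0.17, 0.17, -0.16 and -0.19. Camera with its preset correlation gave adjusted p values of 0.0034, 0.0034, 0.0034 and 0.0065. With an estimated correlation the adjusted p was 0.21 for each. In PAEC no chromosome other than the mitochondrial one passed with the preset correlation. The lowest adjusted p of the others was 0.19 (camera, Y chromosome). With an estimated correlation the mitochondrial set did not pass in PAEC either (camera, adjusted p = 0.57).

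The chromosome medians were compared with gene density, a relation looked for after their differences were seen. Over 21 chromosomes, the median log2 fold change of genes above 1 on the log2 CPM scale rose with the number of genes per Mb in PASMC (Pearson r = 0.82, permutation p = 1e-05, the smallest that 100000 permutations can give; Spearman rho = 0.83, permutation p = 2e-05; adjusted over 3 such relations, 1.5e-05 and 6e-05). In PAEC it fell (r = -0.58, permutation p = 0.0069; rho = -0.58, permutation p = 0.0063; both adjusted to the same values). These permutations shuffled density over chromosomes, so their p-values do not measure the spread between libraries. Without the 2 chromosomes farthest from the median density, r was 0.85 in PASMC and -0.65 in PAEC. Within chromosomes the Spearman correlation, across genes, of log2 fold change with the number of genes within 500 kb on either side was above 0 on 21 of 21 chromosomes in PASMC (median 0.28) and below 0 on 20 of 21 in PAEC (median -0.10). Without PAEC siControl replicate 1, the median in PAEC was -0.050, below 0 on 17 of 21. The 4226 genes with at most 15 genes in this window had a median log2 fold change of -0.14 in PASMC, and the 3648 genes with at least 27 had 0.19. In PAEC the corresponding medians were 0.048 and -0.059.

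**Figure D4:**
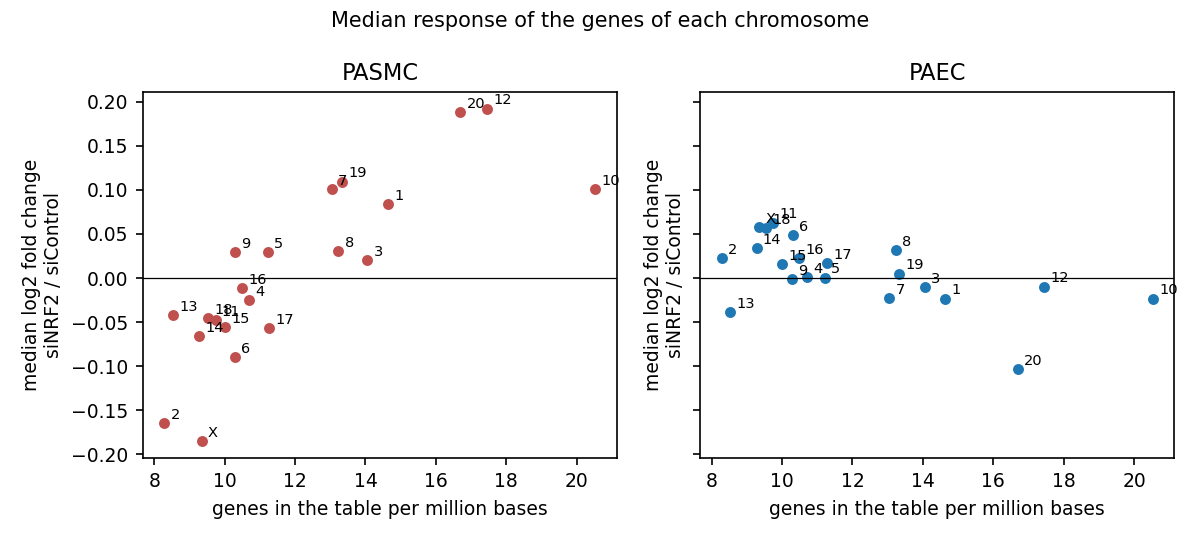
Median log2 fold change of siNRF2 over siControl (y axis) of the genes of each of 21 chromosomes, by the number of genes in the count table per Mb (x axis), in PASMC (left) and PAEC (right). The medians rise with gene density in PASMC (r = 0.82) and fall in PAEC (r = -0.58).

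Single libraries of 1 group also differed along this trend. Against the mean of the other 2 libraries of its group, PAEC siControl replicate 3 had a median within-chromosome correlation with gene density of -0.24, below 0 on 21 of 21 chromosomes, and PASMC siNRF2 replicate 1 had 0.22, above 0 on 20. Per library, the slope of log2 CPM on log2 local gene density, relative to the mean of the cell type, averaged -0.067 ± 0.026 in PASMC siControl and 0.067 ± 0.032 in PASMC siNRF2, and 0.021 ± 0.047 in PAEC siControl and -0.021 ± 0.021 in PAEC siNRF2 (mean ± SD, n = 3). In PAEC the slopes overlapped between the siRNAs, from -0.030 to 0.063 in siControl and from -0.041 to 0.00082 in siNRF2. The trend in PAEC is therefore not shown to go with the siRNA. The mitochondrial level moved against the density slope. Over the deviations of the 12 libraries from their group means, Pearson's r was -0.92 (permutation p = 0.0038) and Spearman's rho -0.87 (permutation p = 0.0068), with 1 such relation computed. Without the 2 libraries with the slopes farthest from the median, r was -0.84.

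**Figure D5:**
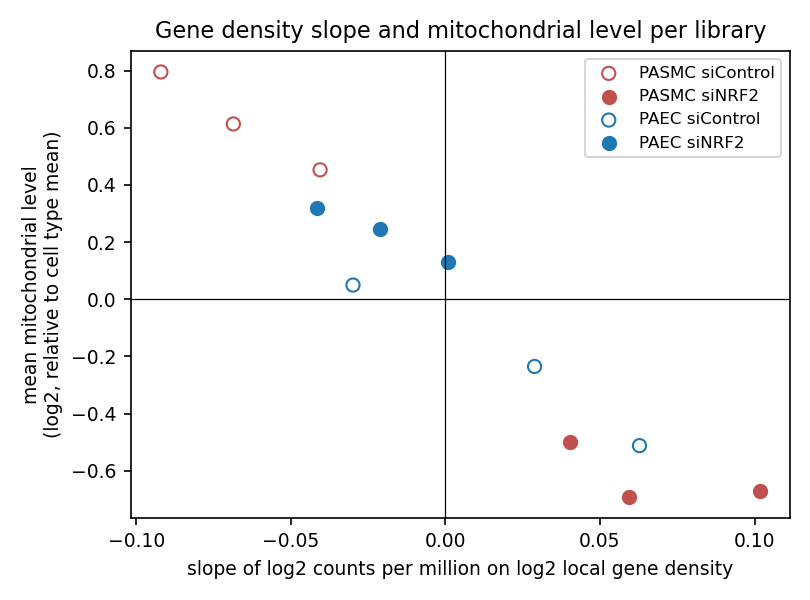
Mean level of the 15 longer mitochondrial genes in each of 12 libraries (y axis, log2, relative to the mean of the cell type) by the slope of log2 CPM on log2 local gene density (x axis), in PASMC (red) and PAEC (blue), with siControl as open and siNRF2 as filled circles. The mitochondrial level tends to be lower in libraries with a higher slope (r = -0.92 over deviations from group means), though not for every pair of libraries of a group.

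The cell types were also compared with each other under control siRNA. Of 14584 genes, 4046 were higher in PAEC and 4123 higher in PASMC (edgeR, adjusted p under 0.05, n = 3 per group), and 1675 and 1680 of these differed by at least 2-fold. With library totals in place of TMM factors, 2125 were higher in PAEC and 7488 higher in PASMC, as that scaling moved the median log2 difference of all genes by -0.44. At least 10 counts in every PASMC library and 0 in every PAEC library were found for 59 genes, and the reverse for 13. Neighbouring genes often differed together, in 108 regions against a mean of 38.9 with shuffled calls (permutation p = 0.0010, the smallest possible). On chromosome 10, 7 genes between 84131495 and 84202688 were all higher in PAEC, with log2 differences from 4.48 to 5.86. On chromosome 3, 8 genes between 61433863 and 61670282 were all higher in PASMC, and 2 of them had no counts in at least 1 of the groups compared.

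Genes of the Y chromosome were counted in PAEC and hardly in PASMC. They took 257 ± 34.4 CPM of the library total in PAEC siControl and 314 ± 8.78 in PAEC siNRF2, against 3.20 ± 0.310 in PASMC siControl and 1.63 ± 0.218 in PASMC siNRF2 (mean ± SD, n = 3). Of the 7 Y genes tested, 5 had 0 counts in all 6 PASMC libraries, and 3 counts of their summed total, the limit that a count of 0 allows, set a bound of 0.0162 CPM for each, for counting error only. All 7 had at least 10 counts in every PAEC library. On the X chromosome, 3 neighbouring genes between 74304292 and 74345507 had 43565 counts in the 6 PASMC libraries and 10 in the 6 PAEC libraries. The difference between the cell types, and the difference in their responses, therefore coincide with a difference in Y-linked counts.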

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

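The test of mixing between cell types was chosen after its result was seen, as were the fit that removes the trend with gene density and the comparison of mitochondrial genes with the median of other genes. The tests of gene density, copy number and scaling were set before their values were computed, but after the chromosome and mitochondrial shifts had been seen.

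The siRNA effect differed between the cell types for 4239 genes by the interaction test. Of 100 splits of the siRNA labels within cell types, 1, the real one, called as many, and the highest of the others called 2050. That highest split kept the real labels in PASMC. Splits that mix the labels of a cell type move its siRNA effect into the spread within groups, which lowers their calls. They therefore cannot exclude chance assignment as the source of this number. For the separate comparisons, 10 splits of 3 against 3 cannot give a share under 0.05. The real split called 4479 genes in PASMC, where the highest other split called 0, and 3607 in PAEC, where the highest other called 2. For the baseline difference these numbers were 8169 and 0. In each case 1 split, the real one, called as many genes.

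In the separate comparisons of the siRNAs, 619 genes were called in opposite directions in the cell types. ENSRNOG00000007089 rose more in PAEC (interaction log2 fold change 1.54) and ENSRNOG00000029668 fell more in PAEC (-2.49). All genes of 6 regions differed in their response, a number that was 11 without PASMC siControl replicate 3 and 10 without PAEC siControl replicate 3. The 4 genes of the chromosome 20 region had a median log2 fold change of -2.39 in PAEC and 1.01 in PASMC.

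On 4 chromosomes (2, 12, 20 and X) the set test with its preset correlation found a different response in the cell types, and none of these passed with an estimated correlation (adjusted p from 0.15 to 0.25, camera). Causes were weighed on the shifts in PASMC, for which the bounds were set. Copy number as the whole cause would move the genes of a chromosome alike. In PASMC the difference between gene-dense and gene-sparse genes within the most shifted chromosomes was 92.8% of the spread between these chromosomes. This was just short of the bound set against copy number. For the interaction the same measure was -100.1%, negative as gene-dense genes had the lower values, and its size reached that bound. With the density trend removed from the PASMC fold changes, 68.1% of the SD of the chromosome medians was left, between the bounds set. For the interaction 65.0% was left. With the trend removed from each library in the fit, the PASMC medians went from 0.17 to 0.10 on chromosome 12, from 0.17 to 0.066 on 20, from -0.16 to -0.11 on 2 and from -0.19 to -0.16 on X. None passed (adjusted p from 0.11 to 0.19, camera on test statistics). The medians became smaller, least so on X. For the PASMC shifts, copy number and the density trend cannot be told apart here, as both PASMC values lie between the bounds set. No bounds were set for the interaction. A response to the siRNA stays open and untested.

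The interaction was called for 14 of the 15 longer mitochondrial genes, of which 14 fell in PASMC and 5 rose in PAEC. Under DESeq2 size factors and library totals at least 100.2% of the median fall in PASMC was left, but these moved the PASMC comparison too little to test scaling. A factor that moves all genes of a library alike cannot change the level of these genes relative to the median of other genes. That level differed by -1.27 on the log2 scale (4.12 ± 0.17 in siControl and 2.85 ± 0.11 in siNRF2, mean ± SD, n = 3, no overlap). This argues against such a factor for the fall in PASMC. The value nearly restates the fold change after TMM, which already removes such a factor, so it is no separate support for the fall. A candidate explanation is a library-wide trend that also varies between replicates of 1 group, since within groups the mitochondrial level followed the density slope (r = -0.92, permutation p = 0.0038). Extended to the difference between groups, that relation predicts 54.5% of the fall in PASMC and 44.6% of the higher level in PAEC, and the remainder, and whether base composition, RNA quality or a response to the siRNA lies behind the trend, stays open and untested.

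Y-linked counts were found in PAEC and hardly in PASMC, a difference that runs with the cell type. Mixing of PAEC material into PASMC libraries would bring the Y genes in the proportions seen in PAEC, but 91.9% of the 443 Y counts in PASMC lay in 1 gene, which held 0.509% of Y counts in PAEC. The tables leave open that the PASMC came from animals without a Y chromosome, or had lost it in culture, and neither was tested. Sex or donor may therefore contribute to the baseline difference and to the interaction.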

How the results depend on the processing

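The gene density offset, the fits without mitochondrial genes and the alternatives for gene groups and regions were added after the data were seen, as were library totals, limma voom and the filter of 10 counts for the genes shared between or opposite in the cell types. Other settings for the gene lists and for the siRNA target were not run, since no gene could be named. Counts of called genes stayed within 1.5 times of 4479 in PASMC, 3607 in PAEC, 4239 for the interaction and 8169 for the baseline under each other scaling, tool, filter and set of libraries tried. Stricter thresholds, which by construction call fewer genes, moved them further, except the baseline at an adjusted p under 0.01. At an adjusted p under 0.01 they were 2783, 2248, 2426 and 6526, with 500 genes shared in direction and 220 opposite, and with at least a 2-fold change 337, 586, 906 and 3355. Leaving out 1 library gave 3157 to 4261 in PASMC, 2738 to 3717 in PAEC, 3332 to 4808 for the interaction, 7444 to 7941 for the baseline, 717 to 982 shared and 407 to 927 opposite genes. The lowest number of opposite genes came without PAEC siControl replicate 2, and the cause was not tested. With library totals, 1979 genes rose and 2483 fell in PASMC, 1351 rose and 2228 fell in PAEC, and 341 rose and 573 fell in both, against 459 and 452. The 4 genes printed by ID stayed called in both cell types under all 16 alternatives of each. Replicate numbers did not pair the samples, as same-numbered libraries had deviations correlated at -0.037 to 0.013 in PASMC and -0.058 to -0.021 in PAEC, and not every library correlated best with its own number. With the replicate number as a block, 4286, 3362, 4078 and 8005 genes were called, and 9 mitochondrial genes in PAEC against 5. With the gene density offset the counts were 3994, 3710 and 3781, of which 3320, 3396 and 3138 were also called without it, with 986 shared and 505 opposite genes. Independent lists of those sizes would give 507.9 opposite genes. The chromosome and mitochondrial set tests did not pass with an estimated correlation. In simulated PASMC data 52.2% of 2-fold changes were recovered at this depth and number of replicates. Of 4-fold changes 83.3% were recovered. Changes of 2-fold or less, and some larger ones, can therefore be missed. These shares need not hold for the data, where far more genes were called than were changed in the simulation.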

Other observations

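Genes at least 8-fold higher in 1 cell type, under both siRNAs, were compared between siNRF2 and siControl. This definition replaced, after the first results were seen, one on siControl libraries alone. Of 419 genes enriched in PASMC, 51 fell and 11 rose in PAEC given the NRF2 siRNA. Their log2 fold changes in PAEC had a median of 0 and a mean of -0.61. The list was selected for low levels in PAEC, and a gene without counts in either PAEC group has a fold change of 0. The median therefore does not show that the set stayed unchanged. In PASMC themselves, 22 of these genes fell and 20 rose. Of 229 genes enriched in PAEC, 25 fell and 24 rose in PAEC, and 32 fell and 16 rose in PASMC. The set of PASMC-enriched genes did not pass the test against other genes in PAEC by camera (adjusted p = 0.30, and 0.18 with an estimated correlation), while fry, which tests direction in the set alone, gave an adjusted p of 0.00028. These splits depended on the tool and on how the lists were set. For PASMC-enriched genes in PAEC, 33 fell and 1 rose with limma voom, 28 fell and 0 rose with only the 6 PAEC libraries in the fit, 51 fell and 45 rose with the list set on siControl libraries alone, and 148 fell and 11 rose with it set on siNRF2 libraries alone. For PASMC-enriched genes in PASMC, 50 fell and 36 rose with voom and 49 and 35 with only the 6 PASMC libraries, 39 and 21 with the siControl list, and 27 and 41 with the siNRF2 list. Without PASMC siControl replicate 2 13 fell and 14 rose, and without PASMC siNRF2 replicate 1 13 fell and 10 rose. For PAEC-enriched genes in PASMC, 17 fell and 8 rose with voom, 14 and 7 with only the 6 libraries, 33 and 50 with the siControl list, and 58 and 17 with the siNRF2 list. For PAEC-enriched genes in PAEC, 45 fell and 38 rose with voom, 42 and 32 with only the 6 libraries, 50 and 24 with the siControl list, and 26 and 50 with the siNRF2 list. Without PAEC siControl replicate 2 16 fell and 18 rose, and without PAEC siNRF2 replicate 3 14 fell and 19 rose. The lists set on 1 siRNA share libraries with the comparison, which draws them in opposite directions. The lists set under both siRNAs were also chosen on the libraries compared, so their counts and tests are not independent of that choice.

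Further regions that fell in PAEC lay on chromosome 1 from 252906234 to 252946170, with a median log2 fold change of -1.66 over 3 genes. Another 3 genes each fell on chromosome 6 from 45655954 to 46631983 and on chromosome 19 from 52051267 to 52112629. In both of these, 1 gene had no counts in PAEC siNRF2, so no median is given. The first gene of the chromosome 1 region, at 252906234 to 252911382, went from 30.6 ± 2.17 to 8.71 ± 2.0 CPM in PAEC and from 392 ± 26.6 to 559 ± 38.4 CPM in PASMC (mean ± SD, n = 3), and its responses differed by -2.33 on the log2 scale (SE 0.16, adjusted p = 3.8e-08, edgeR). The test of the 1088 single-exon genes as a group did not pass in either cell type (camera, adjusted p = 0.91 in PASMC and 0.96 in PAEC).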
